A study of Arabidopsis thaliana with 29 samples.

How the data were processed

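RNA of leaves was sequenced in 29 libraries as paired reads of 100 bases, and 27 of these libraries, in 10 groups, enter 7 comparisons. Per the submitters' processing notes, reads were aligned with TopHat2 and quantified and compared with Cufflinks and Cuffdiff on the TAIR10 genome. The versions, the annotation, the filters, the strand setting and the number of reads per library are not stated, so depth is unknown and genes that overlap on opposite strands could not be told apart. Per the file headers, the authors computed FPKM values with Cuffdiff as 1 value per gene and group, separately for each comparison. The Col wild type FPKM values of the 5 constitutive tables deposited by the authors differ by nearly 1 factor per table (medians 1, 0.969, 0.936, 1.04 and 0.935), to within 1% for at least 99.98% of the genes with FPKM above 1. Per the file headers, the p-value of each gene is the authors' uncorrected Cuffdiff p-value and the q-value is its Benjamini-Hochberg adjustment, with 5e-05 as the smallest p-value. Per the file headers, the deposited score of each gene is Cuffdiff's test statistic. The log2 column of the deposited tables has cells that are not numbers and was not used, and log2 fold changes were computed here from the FPKM values as line over control.

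Each table has 32650 entries, of which 32270 could be given a locus tag with the TAIR10.1 annotation, which was used for names only. The positions in the tables are those of stretches of overlapping reads. Their starts are counted from 0, since 8881 of 21762 entries named by locus tag start at the annotated gene start when 1 is added and 91 do so as listed, and positions are printed with 1 added. Among the entries 1238 join several genes, and these were kept in the main analysis and left out as an alternative. A gene was tested where the table marks its test as made, and called where the authors' q was below 0.05. Of the 24 gene lists, with 356 members, 355 members were measured (SEP3 was not). The called members of each list were compared with all other tested genes by a two-sided Fisher's exact test per direction for lists with at least 4 tested members, Benjamini-Hochberg adjusted over the lists and directions of a comparison (44 or 46 tests). These tests treat genes as independent, which genes that move together are not. The count adjusted over the list alone applies the same adjustment to the authors' p-values of the list members. Medians were placed among 10000 random lists of the same size matched on mean FPKM in 20 bins.

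Overlaps of called genes were counted per direction among genes tested in both comparisons, with Fisher's exact test adjusted over the 21 pairs, and set beside n1 × n2 / N. For the 10 pairs that share the Col wild type libraries, 100 simulations drew unchanged lines against shared control values with the recomputed standard errors, and only their covariance is given. The difference between both times was tested per gene as the difference of the log2 fold changes over its standard error, against the normal distribution, with Benjamini-Hochberg adjustment. The deposited p-values do not follow from the deposited test statistics, so the standard errors were recomputed from the p-values, as provided for beforehand. At the smallest p-value this gives an upper bound of the standard error. Tested on simulated data with 200 planted differences, this procedure recovered 26.9% of log2 differences of 0.5, 58.2% of 1 and 81.8% of 2, with 4 calls among unchanged genes. The simulated p-values were made from their standard errors. The simulation therefore cannot show whether standard errors from the deposited p-values are right. On shuffled genes the list test gave 0 calls of 44, 0 of 46 and 1 of 46 for the comparisons of Dex-GDU1 at 7 h, at 25 h and of gdu1-1D.

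The groups, comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names every GDU gene in every comparison; the 10 called genes with the largest log2 fold change each way for Dex-GDU1 and gdu1-1D, and 5 each way for the other lines, among genes with a symbol and FPKM of at least 5 in a group; up to 4 called members with the largest change of each list that passed or had at least 3 called members; and the 10 genes called in the same direction in the most comparisons, by the smallest sum of ranks of q. Ties in that sum were broken by the mean absolute change, a choice made in the script and not in the rule. The text gives part of the genes so named. The alternatives were q below 0.01, FPKM of at least 1, a minimum log2 change of 1 on 3 scales (plain, with a pseudocount of 1, and centred on the median gene), adjustment recomputed over expressed genes, and the other standard error. Leaving out entries that join several genes was added after seeing the data, as were lists of cytokinin-induced and touch-induced genes (23 genes, all measured) for the tests in the closing section, the test of the GDU list without the over-expressed gene, and the levels of endoplasmic reticulum stress, iron and cytokinin-induced genes in each line at both times. The libraries 35S-GDU1 and 35S-GDU3 were left out, since the tables used hold no comparison of them. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.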

Results

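Leaf transcripts of Arabidopsis thaliana (Columbia) were measured by RNA sequencing in plants that over-express members of the GLUTAMINE DUMPER (GDU) family, small plant membrane proteins whose over-expression is known to alter amino acid export. The series holds 29 libraries in 12 groups, each library made from the leaves of 4 to 6 plants grown on soil for 23 days (4 weeks in the series description) in cycles of 16 h light and 8 h dark at 22 °C. Dex-GDU1 plants carry a dexamethasone-inducible GDU1 gene, and 4c-S7 is their parental line. Both lines were sprayed with 100 µM dexamethasone 5 h after dawn and sampled 7 h and 25 h later, with 3 Dex-GDU1 and 4 4c-S7 libraries at each time. For all sprayed plants the labels also give Silwet at 300 ppm and a humidity dome for 7 h. The series holds no unsprayed group of either line, so each of these comparisons sets line against line and includes lasting differences between them. The unsprayed constitutive lines were gdu1-1D, a dominant GDU1 over-expressor, with 3 libraries, and lines labelled 35S-GDU2, 35S-GDU4, 35S-GDU5 and 35S-GDU6, with 2 libraries each. All of these were compared with the same 2 Col wild type libraries. The groups 35S-GDU1 and 35S-GDU3, with 1 library each, were not analysed here. The authors' deposited tables give 1 FPKM (fragments normalised to transcript length and to the mapped fragments of the library) value per gene and group, so that no spread between libraries and no depth per library could be given. The labels number the libraries as biological replicates but do not say how the plant pools were separated. Each library was sequenced in 2 runs, and nothing says whether the authors' test took these runs as replicates. The authors' p-values measure a spread between libraries or runs, part or all of which may be technical.

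The over-expressed gene was examined first, as a check of the labels. GDU1 (AT4G31730, chromosome 4, 15361091 to 15361850 on TAIR10) rose in Dex-GDU1 from 23.3 to 5281 FPKM at 7 h and from 6.52 to 3362 FPKM at 25 h in the authors' deposited tables. In gdu1-1D it rose from 5.19 to 294 FPKM, or 56.7-fold, in the authors' deposited table. GDU2 (AT4G25760, chromosome 4, 13116076 to 13116838) rose from 2.72 to 4706 FPKM in 35S-GDU2, and GDU5 (AT5G24920, chromosome 5, 8584665 to 8585275) rose from 2.86 to 3198 FPKM in 35S-GDU5, in the authors' deposited tables. GDU6 (AT3G30725, chromosome 3, 12352509 to 12352844) rose from 9.14 to 30183 FPKM in 35S-GDU6 in the authors' deposited table, and held 3.46% of the FPKM sum of the tested genes there. GDU4 (AT2G24762) was not called in the libraries labelled 35S-GDU4, at 8.72 FPKM in Col wild type and 10.9 FPKM in the line with a q of 0.949 in the authors' deposited table. Its values come from a stretch of overlapping reads on chromosome 2, from 10559384 to 10708146, that 47 genes of the table share. The effects in those libraries are therefore given below for the label only, since no rise of GDU4 was measured in them.

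Other family members also changed in some lines. GDU6 rose to 36.4 FPKM in 35S-GDU2 and to 60.6 FPKM in 35S-GDU5, against 9.46 and 10.1 FPKM in Col wild type, and fell from 9.78 to 6.76 FPKM in gdu1-1D (q 0.0425), in the authors' deposited tables. GDU1 rose 2.58-fold in 35S-GDU2, 1.63-fold in 35S-GDU5 and 1.57-fold in 35S-GDU6. GDU3 rose by a log2 fold change of 1.16 in 35S-GDU5, 1.04 in 35S-GDU6, 0.75 in Dex-GDU1 at 25 h, 0.58 in 35S-GDU2 and 0.45 in the libraries labelled 35S-GDU4. GDU7 fell in gdu1-1D (log2 fold change -2.30) and in 35S-GDU5 (-2.51), from levels of 3.24 and 3.36 FPKM in the authors' deposited tables. In the libraries labelled 35S-GDU4, GDU2 rose from 2.63 to 12.0 FPKM and GDU5 from 2.58 to 5.28 FPKM, and in 35S-GDU5 GDU2 rose from 2.92 to 7.23 FPKM, in the authors' deposited tables. As a list, the family passed in 35S-GDU2 alone of the 7 comparisons, with 4 higher and 0 lower of 7 (5 and 1 adjusted over the list alone, adjusted p 0.0314). GDU2 itself is 1 of the 4, and without it 3 of 6 were higher (Fisher's exact p 0.0435, not adjusted over lists). Without the gene of the label, 3 of 6 were also higher in the libraries labelled 35S-GDU4 (exact p 0.0144) and 4 of 6 in 35S-GDU5, with 1 lower (exact p 0.0595), again not adjusted over lists. The lines were not tested against each other, so the list result cannot be called particular to 35S-GDU2.

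**Figure D1:**
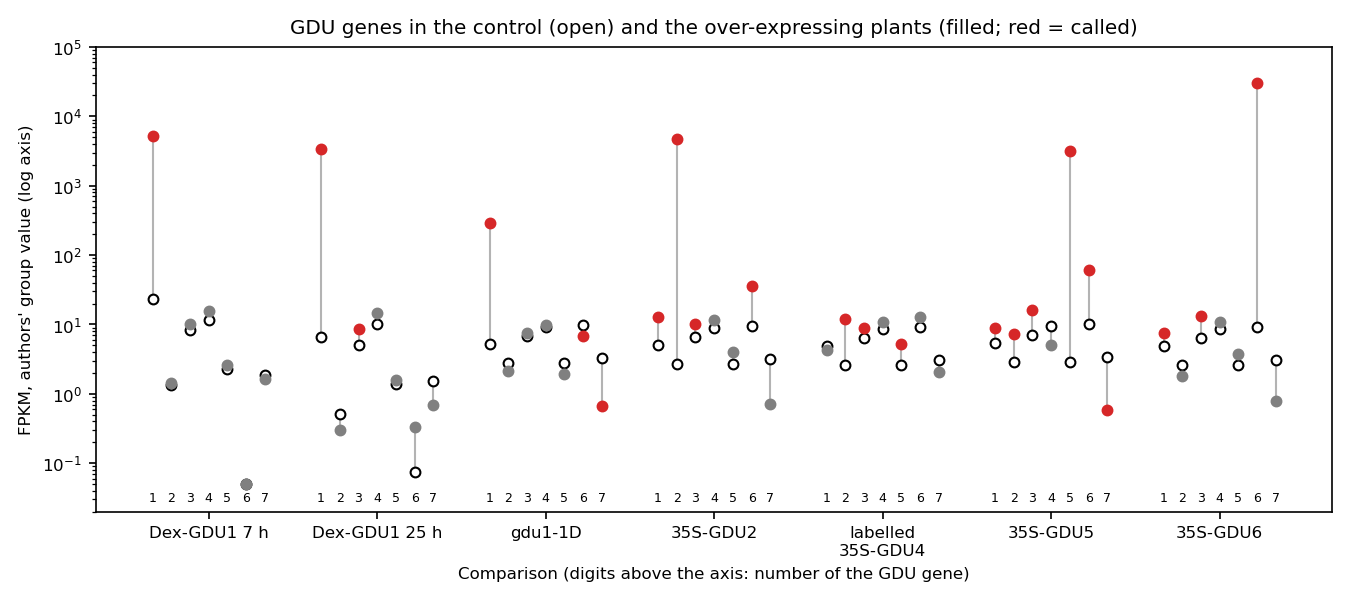
FPKM (log axis) of the 7 GDU genes in the control (open circles) and in the over-expressing plants (filled circles, red where called at the authors' q below 0.05, grey where not) for each of the 7 comparisons; GDU6, listed at 0 in both groups of Dex-GDU1 at 7 h, is drawn near the bottom of the axis. The gene of the label is the highest point in every comparison except the one labelled 35S-GDU4, where GDU4 was at 10.9 FPKM.

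The comparison of Dex-GDU1 with 4c-S7 at 7 h addresses the early response to GDU1 induction. It cannot separate that response from lasting differences between the lines or from handling. Of 12 touch-induced genes, a list added after seeing the data, 10 were called higher and 1 lower (Fisher's exact adjusted p 5.81e-09 for the higher direction). Several of the 12 also stand in the fixed lists, and SZF1 is among the largest rises named below. That p-value therefore rests partly on genes already seen to rise and gives no separate support for handling. At 7 h, genes of abscisic acid, drought and cold response, jasmonate genes and genes of pattern-triggered immunity were called higher more often than other genes. Salicylic acid and endoplasmic reticulum stress genes were called lower more often than other genes. Apart from GDU1 itself, the largest rises among well expressed genes were those of CBF1, a cold-response regulator (log2 fold change 2.94, SE 0.81), CYP707A3, an abscisic acid hydroxylase (2.59, SE 0.64), and the ethylene response factor gene ERF6 (2.44, SE 0.60). HSPRO2 (log2 fold change 2.40), ERF5 (2.37, SE 0.58), ORA47 (2.33), DIC2 (2.12), BT5 (2.08) and SZF1 (1.88) followed. The salicylic acid marker gene PR1 fell from 18.1 to 4.13 FPKM in the authors' deposited table (log2 fold change -2.13, SE 0.53). Standard errors of log2 fold changes, here and below, were recomputed from the deposited p-values. Where the p-value is the smallest the tool can give, they are upper bounds that scale with the fold change and are not a measured spread. ARD3 (log2 fold change -2.13), CHI (AT2G43570, -1.02) and LTP3 (-0.96) also fell. Larger falls than that of PR1 were those of SNOR105, MIR171c, MIR168a and the joined entries of AT2G14595 with PRB1 and of AGL68 with AGL69.

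By the fixed lists, 14 of the 17 tested abscisic acid, drought and cold genes rose and 0 fell at 7 h (14 and 0 adjusted over the list alone), with an adjusted p of 3.46e-11 by Fisher's exact test against all other tested genes. CBF2 and NCED3, which encodes a key enzyme of abscisic acid synthesis, rose by log2 fold changes of 1.75 and 1.74. Of 22 jasmonate genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone, adjusted p 7.14e-06), among them the regulator MYC2 (log2 fold change 0.82) and LOX4 (0.68). Of 19 genes of pattern-triggered immunity and camalexin, 9 rose and 1 fell (12 and 2 adjusted over the list alone, adjusted p 0.000107), led by WRKY40 (log2 fold change 1.75), WRKY53 (1.67) and CYP81F2 (1.28). Salicylic acid genes went the other way, with 5 higher and 12 lower of 28 (7 and 14 adjusted over the list alone), a median log2 fold change of -0.24 and an adjusted p of 4.11e-06 for the lower direction. Among them DLO1, which encodes a salicylic acid hydroxylase, fell by 1.27 on the log2 scale and PR2 by 0.76, while CBP60G, a regulator of salicylic acid synthesis, rose by 1.05. Of 13 endoplasmic reticulum stress genes, 1 rose and 8 fell (1 and 9 adjusted over the list alone, adjusted p 7.14e-06), with BIP3, an endoplasmic reticulum chaperone gene, at a log2 fold change of -1.02 and BZIP60 at 0.32. Of 10 iron genes, 0 rose and 6 fell (1 and 6 adjusted over the list alone, adjusted p 0.000163), with BHLH38 at -0.39.

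Smaller rises at 7 h took in 8 of 25 amino acid transporter genes (9 adjusted over the list alone, adjusted p 0.00464, and 0.0626 at q below 0.01), with AAP4 at a log2 fold change of 0.65 and PROT1 at 0.37. A single transporter gene, CAT3, fell (-0.25; 2 fell adjusted over the list alone). Photosynthesis genes rose in 7 of 21 cases (7 adjusted over the list alone, adjusted p 0.00605), all by less than 1 on the log2 scale, with LHCB1.1, a light-harvesting protein gene, at 0.58. Glucosinolate synthesis genes rose in 7 of 18 cases (8 adjusted over the list alone, adjusted p 0.00288) and auxin response genes in 5 of 8 (6 adjusted over the list alone, adjusted p 0.00144). Senescence genes rose in 5 of 11 cases, with 1 lower (6 and 1 adjusted over the list alone, adjusted p 0.00605). The lists of ethylene (4 higher and 1 lower of 14, and 4 and 1 adjusted over the list alone), circadian clock (4 and 0 of 12, and 4 and 0), oxidative stress (4 and 1 of 14, and 4 and 1) and nitrogen and amino acid metabolism genes (3 and 2 of 26, and 6 and 2) did not pass the list test. Neither did those of heat shock (1 and 1 of 6, and 1 and 2), flavonoid (0 and 1 of 4, and 0 and 1), sugar starvation (2 and 0 of 4, and 3 and 0) and vascular marker genes (2 and 0 of 7, and 2 and 0). No marker gene of guard cells (5 tested), of epidermis and trichomes (4), of roots (2) or of flowers (3) was called at 7 h by Cuffdiff, with 4592 genes at an unadjusted p below 0.05 in that table. In all, 2791 of 17496 tested genes were called at the authors' q below 0.05, of which 1533 were higher and 1258 lower, and 145 and 35 of them changed at least 2-fold. At q below 0.01 the count was 1851.

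The comparison at 25 h addresses the later response to GDU1 induction, with the same limits. Abscisic acid, immunity and senescence genes rose, salicylic acid and endoplasmic reticulum stress genes were now higher than in 4c-S7, and abscisic acid receptor and cytokinin response regulator genes were among the largest falls. BSMT1, a salicylic acid methyltransferase gene, rose 22.8-fold (log2 fold change 4.51, SE 1.11), the lipid transfer protein genes LTP4 and LTP3 rose 21.6-fold and 18.3-fold. KIN1, AFP1, GolS2, LEA7 and HAI2, all linked to abscisic acid or drought, rose between 17.1-fold and 19.9-fold. NATA1, an ornithine acetyltransferase gene, rose by a log2 fold change of 3.80. The abscisic acid receptor genes PYL6 (log2 fold change -3.1, SE 0.76) and PYL4 (-2.16), the response regulator genes ARR15 (-1.80) and ARR6 (-1.51), and the expansin gene EXPA1 (-1.75) fell. GASA9, one of the guard-cell markers, fell by 1.51 on the log2 scale.

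At 25 h, 19 of 20 abscisic acid, drought and cold genes rose and 0 fell (20 and 0 adjusted over the list alone, median log2 fold change 1.97, adjusted p 8.66e-10), with RD29B at 5.47 and HAI1 at 3.17. The guard-cell markers went the other way, 4 of 5 being lower and 0 higher (4 and 0 adjusted over the list alone, median -0.47, adjusted p 0.0276). Of 28 salicylic acid genes 26 rose and 0 fell (26 and 0 adjusted over the list alone, median 1.24, adjusted p 1.30e-12), including GRX480 (5.74-fold), NIMIN1 (4.61-fold) and ALD1 (4.30-fold), an enzyme gene of pipecolic acid synthesis. Of 23 jasmonate genes, 20 rose and 1 fell (20 and 1 adjusted over the list alone, adjusted p 7.35e-09), led by JAZ7 (3.48) and CORI3 (2.25). Of 19 pattern-triggered immunity genes, 16 rose and 2 fell (16 and 2 adjusted over the list alone, adjusted p 8.53e-07), with WRKY53 at 2.83 and WRKY29 at -1.99. Of 12 senescence genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone, adjusted p 1.26e-05), among them the sugar transporter gene SWEET15 (3.28) and the regulator NAP (2.31). Iron deficiency regulators were higher than in 4c-S7, with BHLH38 at 3.04 and BHLH100 at 2.90 in a list of 7 higher and 2 lower of 10 (7 and 2 adjusted over the list alone, adjusted p 0.0119). Endoplasmic reticulum stress genes rose in 10 of 13 cases and fell in 0 (10 and 0 adjusted over the list alone, median 0.37, adjusted p 0.000537).

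Both fixed lists of amino acid genes were higher more often than other genes at 25 h. Of 26 transporter genes, 18 rose and 1 fell (19 and 1 adjusted over the list alone, adjusted p 1.26e-05), with the exporter genes UMAMIT29 (3.25-fold) and UMAMIT18 (2.45-fold), AAP4 (2.38-fold) and GAT1 (2.29-fold) leading. Of 28 nitrogen and amino acid metabolism genes, 14 rose and 5 fell (14 and 5 adjusted over the list alone, adjusted p 0.0123), with the proline synthesis gene P5CS1 at 2.62 and the proline dehydrogenase gene ERD5 at -1.38. Glucosinolate synthesis (15 higher and 0 lower of 18, and 17 and 1 adjusted over the list alone, adjusted p 2.36e-06) and circadian clock genes (12 and 2 of 15, and 12 and 2 adjusted over the list alone, adjusted p 5.69e-05) were also higher more often than other genes. So were ethylene (9 and 2 of 14, and 9 and 2 adjusted over the list alone, adjusted p 0.00809) and vascular marker genes (5 and 0 of 7, and 5 and 0 adjusted over the list alone, adjusted p 0.0334, and 0.0851 at q below 0.01). Photosynthesis genes were called higher less often than other genes, at 0 of 20 with 1 lower (0 and 1 adjusted over the list alone, adjusted p 0.0227, and 0.0557 at q below 0.01), but their median of -0.06 lay at percentile 78.0 of random lists matched on mean FPKM. The heat shock (4 higher and 0 lower of 6, and 4 and 0 adjusted over the list alone), oxidative stress (7 and 3 of 14, and 7 and 3), flavonoid (5 and 3 of 11, and 5 and 3) and flower marker lists (3 and 1 of 4, and 3 and 1) did not pass. In all, 8143 of 17652 tested genes were called, 4329 higher and 3814 lower, with 804 and 153 of them changed at least 2-fold.

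The change of Dex-GDU1 against 4c-S7 was compared between both times directly. The change at each time includes lasting differences between the lines, which cannot be told from induction at that time. The joined entry of AGL68 and AGL69, for example, was lower at both times in the authors' deposited tables. It stood at 1.65 against 9.32 FPKM at 7 h and at 1.34 against 7.02 FPKM at 25 h. A line difference of the same log2 size at both times cancels in the comparison between times. Line differences that vary with the time of sampling do not cancel and cannot be told from induction. Of 17114 genes tested at both, 2951 differed at an adjusted p below 0.05, 1774 with a more positive and 1177 with a more negative change at 25 h. Of the 28 salicylic acid genes, 23 were more positive at 25 h and 0 more negative, with a median difference of 1.31 in log2 fold change. Of these genes 11 were called lower at 7 h and higher at 25 h. PR1 went from a log2 fold change of -2.13 to 1.51, a difference of 3.65 (SE 0.64, adjusted p 7.22e-06). DLO1 went from -1.27 to 1.99 and PR2 from -0.76 to 0.98. Of 13 endoplasmic reticulum stress genes 11 were more positive at 25 h, 6 of them having been lower at 7 h and higher at 25 h. Of 10 iron genes 7 were more positive and 2 more negative, with BHLH38 going from -0.39 to 3.04. BHLH38 stood at 78.0 and 5.73 FPKM in 4c-S7 at 7 h and 25 h and at 59.5 and 47.2 FPKM in Dex-GDU1 in the authors' deposited tables. Relative to all genes, the median iron gene changed between the times by -1.88 in 4c-S7 and by -0.38 in Dex-GDU1, and the median endoplasmic reticulum stress gene by -0.58 and -0.03, so for both lists the difference lay mainly in lower values of the control at 25 h. Abscisic acid genes, raised at both times, were more positive at 25 h in 11 of 17 cases, while 6 of 20 photosynthesis genes and 3 of 5 guard-cell markers were more negative. Across all genes, 248 were called in opposite directions at both times, 137 of them lower at 7 h and higher at 25 h. With the standard error taken from the deposited test statistic in place of the p-value, 398 genes differed, among them 17 salicylic acid, 13 abscisic acid, 7 iron and 2 endoplasmic reticulum stress genes, 1 guard-cell marker and 0 photosynthesis genes.

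**Figure D2:**
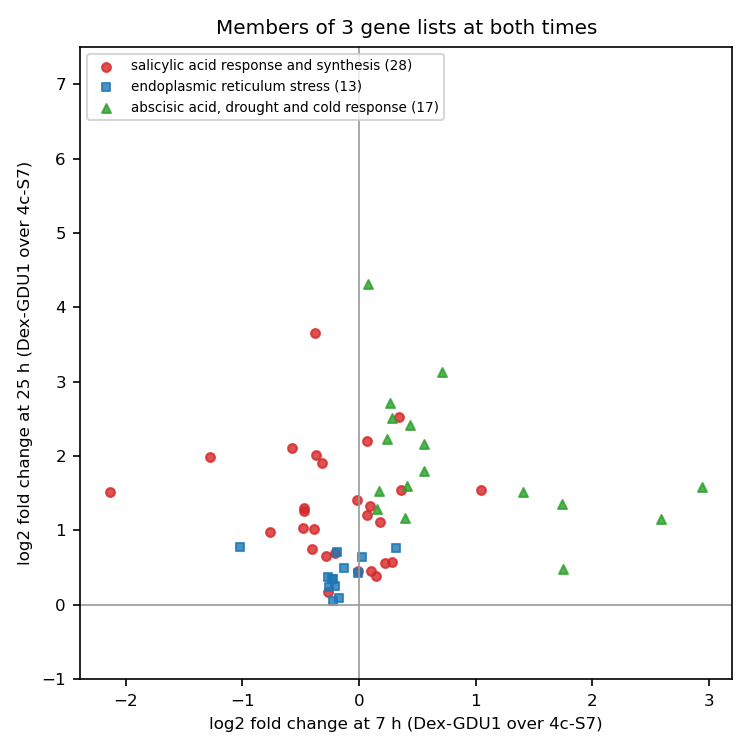
Log2 fold change of Dex-GDU1 over 4c-S7 at 7 h (horizontal axis) and at 25 h (vertical axis) for the members of 3 gene lists tested at both times, 1 point per gene. The median difference of the 28 salicylic acid genes (red circles) between the times was 1.31, and the 17 abscisic acid, drought and cold genes (green triangles) lie above 0 at both times.

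The comparison of gdu1-1D with Col wild type addresses the effect of lasting GDU1 over-expression. It cannot separate that effect from other differences between the line and Col wild type or from handling. Salicylic acid, immunity, jasmonate and endoplasmic reticulum stress genes rose in these leaves, while photosynthesis genes fell. UGT76B1, a glycosyltransferase gene of immune regulation, rose 129-fold (log2 fold change 7.01, SE 1.91), NATA1 82.0-fold, the transcription factor gene WRKY38 53.9-fold and ALD1 41.7-fold. PR1 rose 48.8-fold (log2 fold change 5.61, SE 1.38), from 10.4 to 508 FPKM in the authors' deposited table. The response regulator genes ARR15 (log2 fold change -2.32, SE 0.57) and ARR6 (-1.80), the cytokinin synthesis gene IPT3 (-1.42), the cell wall gene XTH31 (-2.17) and GRP9 (-2.61) were among the largest falls.

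Of the 28 salicylic acid genes tested in gdu1-1D, 27 rose and 0 fell (27 and 0 adjusted over the list alone), with a median log2 fold change of 3.1 and an adjusted p of 5.95e-15. Of 21 immunity genes 18 rose and 1 fell (18 and 1 adjusted over the list alone, adjusted p 1.95e-08), including NHL10 (4.86) and the camalexin synthesis gene PAD3 (4.43), and PROPEP2 was listed at 0 in Col wild type. Of 24 jasmonate genes 21 rose and 0 fell (21 and 0 adjusted over the list alone, adjusted p 5.97e-10), with TAT3 at 4.97 and VSP1 at 4.89. Endoplasmic reticulum stress genes rose in 12 of 13 cases (13 adjusted over the list alone, adjusted p 1.76e-06), with BIP3 at 3.53 and CRT3 at 1.85. Abscisic acid genes rose in 17 of 19 cases (17 adjusted over the list alone, adjusted p 1.74e-08) and senescence genes in 11 of 12 (11 adjusted over the list alone, adjusted p 6.07e-06). Oxidative stress genes rose in 11 of 14 cases and fell in 3 (11 and 3 adjusted over the list alone, adjusted p 8.92e-05). The glutathione transferase genes GSTF6 and GSTF7 rose by log2 fold changes of 3.87 and 3.76. Iron genes (7 higher and 1 lower of 10, and 7 and 1 adjusted over the list alone, adjusted p 0.00813) and sugar starvation genes (5 and 0 of 6, and 5 and 0 adjusted over the list alone, adjusted p 0.0104) were higher more often than other genes. Glucosinolate genes (13 and 2 of 18, and 13 and 2 adjusted over the list alone, adjusted p 7.68e-05) and ethylene genes (9 and 1 of 14, and 9 and 1 adjusted over the list alone, adjusted p 0.00534) were also higher more often than other genes.

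Photosynthesis genes fell in 19 of 20 cases in gdu1-1D and rose in 0 (19 and 0 adjusted over the list alone, median log2 fold change -0.45, adjusted p 6.63e-11), with RBCS1B, a small subunit gene of Rubisco, at -1.02 and the Calvin cycle gene SBPASE at -0.71. Their median lay at percentile 8.95 of 10000 random lists matched on mean FPKM. The guard-cell markers were lower in 3 of 5 cases (3 adjusted over the list alone, median -0.42, adjusted p 0.144). Among flower and floral transition genes FT, FUL and SOC1 rose by log2 fold changes of 2.21, 1.06 and 0.61 and AG fell by 2.25 (3 higher and 1 lower of 4, and 3 and 1 adjusted over the list alone, adjusted p 0.0983). The amino acid importer gene LHT1 rose by 2.15 and CAT1 by 3.71, in a transporter list of 9 higher and 2 lower of 28 that did not pass (8 and 2 adjusted over the list alone, adjusted p 0.405). In nitrogen and amino acid metabolism 14 of 29 genes rose and 7 fell (15 and 7 adjusted over the list alone, adjusted p 0.0104), with P5CS1 at 2.49, the asparagine synthetase gene ASN1 at 2.00 and the glutamine synthetase gene GLN1;1 at 1.84. In all, 7866 of 17694 tested genes were called, 4082 higher and 3784 lower, with 1240 and 161 of them changed at least 2-fold. The 2 Col wild type libraries served all 5 constitutive comparisons, so that a chance value in them recurs in each.

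The comparison of 35S-GDU2 with Col wild type addresses the effect of GDU2 over-expression, with the same limits as for gdu1-1D. Salicylic acid, jasmonate and abscisic acid genes rose in these leaves. Photosynthesis genes and guard-cell markers fell. Apart from GDU2, OSM34 (log2 fold change 5.84, SE 1.69), the peroxidase gene Prx37 (5.79, SE 2.11), VSP1 (5.51, SE 1.36) and PR1 (5.45, SE 1.34) rose most among well expressed genes, and GRP9 (-2.60), ARR15 (-2.50) and NAS3 (-1.79) fell. FSD1, an iron superoxide dismutase gene, rose from 9.40 to 264 FPKM in the authors' deposited table. Salicylic acid genes rose in 25 of 28 cases and fell in 0 (25 and 0 adjusted over the list alone, median 1.82, adjusted p 9.93e-17). Jasmonate genes rose in 18 of 22 cases (18 adjusted over the list alone, adjusted p 3.70e-11) and abscisic acid genes in 17 of 19 (17 adjusted over the list alone, adjusted p 1.07e-11). Immunity genes rose in 15 of 19 cases with 1 lower (16 and 1 adjusted over the list alone, adjusted p 5.23e-09) and endoplasmic reticulum stress genes in 11 of 13 (11 adjusted over the list alone, adjusted p 2.69e-07). Flavonoid and anthocyanin synthesis genes were higher more often than other genes, at 5 higher and 2 lower of 11, with LDOX at 3.01, DFR at 2.90 and the flavonoid gene CHI (AT3G55120) at -0.45 (6 and 3 adjusted over the list alone, adjusted p 0.0376). Iron genes rose in 6 of 10 cases (6 higher and 1 lower adjusted over the list alone, adjusted p 0.00445), with BHLH100 at 2.93.

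Photosynthesis genes fell in 17 of 22 cases in 35S-GDU2 and rose in 0 (18 and 0 adjusted over the list alone, median -0.34, adjusted p 4.57e-12). All 5 guard-cell markers fell (5 adjusted over the list alone, median -0.69, adjusted p 5.54e-05), with GASA9 at -1.17, while the flower list had 3 higher and 0 lower of 4 (3 and 0 adjusted over the list alone, adjusted p 0.0314), with FT at 2.75. Amino acid transporters did not pass, with 7 higher and 2 lower of 25 (7 and 3 adjusted over the list alone, adjusted p 0.175), and AAP6 fell by 0.75 on the log2 scale. Nitrogen and amino acid metabolism genes were lower more often than other genes, at 8 lower and 7 higher of 28 (10 and 7 adjusted over the list alone, adjusted p 0.0193), although ASN1 rose by 2.15 and P5CS1 by 2.40. In all, 4272 of 17294 tested genes were called, 2513 higher and 1759 lower, with 818 and 120 of them changed at least 2-fold.

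The libraries labelled 35S-GDU4 were compared with Col wild type to address the effect of GDU4 over-expression, although GDU4 was not raised in them. In these libraries jasmonate, immunity and abscisic acid genes were called higher, and salicylic acid genes lower, more often than other genes. WRKY40 rose 27.8-fold (log2 fold change 4.80, SE 1.18), PHI-1 27.2-fold, BT2 19.1-fold, CYP707A3 18.5-fold and WRKY53 18.1-fold, and ERF6 and LOX4 rose 15.9-fold and 16.0-fold. PR2 fell from 50.9 to 9.02 FPKM in the authors' deposited table (log2 fold change -2.50, SE 0.62), and QQS (-2.12) and CHI (AT2G43570, -1.94) also fell. Jasmonate genes rose in 15 of 22 cases and fell in 0 (15 and 1 adjusted over the list alone, adjusted p 2.16e-09). Immunity genes rose in 11 of 17 cases with 1 lower (11 and 2 adjusted over the list alone, adjusted p 6.87e-07). Abscisic acid genes rose in 9 of 16 cases with 1 lower (10 and 2 adjusted over the list alone, adjusted p 4.77e-05). Flavonoid genes rose in 7 of 11 cases (7 adjusted over the list alone, adjusted p 0.000158), with DFR at 2.61. Salicylic acid genes were lower in 12 of 24 cases and higher in 2 (14 and 4 adjusted over the list alone, median -0.48, adjusted p 3.54e-08), with DLO1 at -2.05, WRKY54 at -1.72 and CBP60G at 2.00. Endoplasmic reticulum stress genes were lower in 5 of 13 cases and higher in 1 (5 and 1 adjusted over the list alone, adjusted p 0.00386), with BIP3 at -1.61 and BZIP60 at 1.19. Iron genes were lower in 4 of 10 cases and higher in 2 (6 and 2 adjusted over the list alone, adjusted p 0.0106), with BHLH39 at -1.75. No photosynthesis gene of 22 was called by Cuffdiff, with 4148 genes at an unadjusted p below 0.05 in that table. Of 24 amino acid transporters 2 were higher and 4 lower (2 and 7 adjusted over the list alone, adjusted p 0.139 for the lower direction). In all, 2612 of 17001 tested genes were called, 1641 higher and 971 lower, with 388 and 107 of them changed at least 2-fold. These calls were made without a measured rise of the gene of the label.

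The comparison of 35S-GDU5 with Col wild type addresses the effect of GDU5 over-expression, with the same limits as for gdu1-1D. It gave the highest count of called genes of the 7 comparisons. Salicylic acid and immunity genes rose, photosynthesis genes fell, and amino acid transporter genes went both ways. PR1 rose 126-fold (log2 fold change 6.98, SE 1.72), from 10.8 to 1359 FPKM in the authors' deposited table, and UGT76B1 104-fold, WRKY38 86.4-fold, NHL10 75.7-fold, WRKY53 73.7-fold and GRX480 54.9-fold. DIN2, GAT1_2.1, GSTU3 and CYP81F4 were called higher and listed at 0 in Col wild type. XTH31 (log2 fold change -3.10, SE 0.76), the trichome patterning gene TRY (-3.08, SE 0.76) and MES7 (-2.96) fell. Of 28 salicylic acid genes 27 rose and 0 fell (27 and 0 adjusted over the list alone, median 3.47, adjusted p 1.77e-12). Of 21 immunity genes 19 rose and 0 fell (20 and 0 adjusted over the list alone, adjusted p 7.57e-08). Of 23 jasmonate genes 20 rose and 1 fell (20 and 1 adjusted over the list alone, adjusted p 9.92e-08). Endoplasmic reticulum stress genes rose in 12 of 13 cases (13 adjusted over the list alone, adjusted p 2.56e-05). Ethylene genes rose in 12 of 16 cases with 1 lower (12 and 1 adjusted over the list alone, adjusted p 0.00103), with ACS2 at 5.76. Abscisic acid genes rose in 15 of 20 cases with 1 lower (15 and 1 adjusted over the list alone, adjusted p 0.00017). Senescence genes rose in 9 of 11 cases (9 adjusted over the list alone, adjusted p 0.00195), with SAG13 at 5.31. All 6 sugar starvation genes rose (6 adjusted over the list alone, adjusted p 0.00248), with the branched-chain amino acid transaminase gene BCAT2 at 5.36.

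Photosynthesis genes fell in 21 of 22 cases in 35S-GDU5 (21 adjusted over the list alone, median log2 fold change -0.94, adjusted p 2.84e-10), with RBCS1B at -1.88 and SBPASE at -1.35. All 5 guard-cell markers fell (5 adjusted over the list alone, median -1.21, adjusted p 0.00462), as did 5 of 7 vascular markers (5 adjusted over the list alone, adjusted p 0.0452, and 0.109 at q below 0.01). In the list of flower and floral transition genes 5 of 7 were higher and 1 lower (5 and 1 adjusted over the list alone, adjusted p 0.0541). Among the latter FT rose by 2.28 and PI by 2.17, AP1 was listed at 0 in Col wild type, and AG fell by 3.07. Of 29 amino acid transporters 12 were higher and 9 lower (12 and 9 adjusted over the list alone, adjusted p 0.263), with CAT1 at 5.42, UMAMIT14 at 3.59 and LHT1 at 3.12. In all, 9980 of 18129 tested genes were called, 5175 higher and 4805 lower, with 2233 and 669 of them changed at least 2-fold.

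The comparison of 35S-GDU6 with Col wild type addresses the effect of GDU6 over-expression, with the same limits as for gdu1-1D. Sugar starvation and jasmonate genes rose with the highest list medians, salicylic acid genes rose as well, and guard-cell markers fell. The amino acid exporter family gene UMAMIT33 rose 83.2-fold (log2 fold change 6.38, SE 1.57), NATA1 67.7-fold and VSP1 63.0-fold, and VSP2 rose from 2.87 to 114 FPKM in the authors' deposited table. ARR15 (log2 fold change -2.82, SE 0.69), PFA-DSP2 (-2.67), GRP9 (-2.67) and IPT3 (-2.27) fell. Of 24 jasmonate genes 19 rose and 0 fell (19 and 0 adjusted over the list alone, median 2.87, adjusted p 5.73e-07). Of 27 salicylic acid genes 26 rose and 1 fell (26 and 1 adjusted over the list alone, median 0.99, adjusted p 1.86e-13). Of 20 abscisic acid genes 17 rose and 0 fell (17 and 0 adjusted over the list alone, adjusted p 5.73e-07). Of 19 immunity genes 16 rose and 0 fell (16 and 0 adjusted over the list alone, adjusted p 1.10e-06). All 5 tested sugar starvation genes rose (5 adjusted over the list alone, median 3.45, adjusted p 0.00554), with ASN1 at 4.84 and SEN1 at 3.74. Senescence genes rose in 10 of 12 cases (10 adjusted over the list alone, adjusted p 0.000336). Of 15 clock genes 10 rose and 3 fell (10 and 3 adjusted over the list alone, adjusted p 0.00509), with PRR5 at 3.41 and LHY at -1.40.

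All 5 guard-cell markers fell in 35S-GDU6 (5 adjusted over the list alone, median -0.64, adjusted p 0.00509), while photosynthesis genes did not pass, with 8 lower and 1 higher of 22 (8 and 1 adjusted over the list alone, adjusted p 0.347). Endoplasmic reticulum stress genes did not pass either, with 4 higher and 0 lower of 13 (4 and 0 adjusted over the list alone, adjusted p 0.93). The flavonoid genes CHS and FLS1 fell by 1.81 and 1.80 on the log2 scale and DFR rose by 1.26, in a list of 2 higher and 4 lower of 10 that did not pass (2 and 4 adjusted over the list alone, adjusted p 0.404). Amino acid transporters were higher in 12 of 25 cases and lower in 5 (13 and 5 adjusted over the list alone, adjusted p 0.0476, 0.0701 at q below 0.01, and 0.0799 among genes with FPKM of at least 1), with CAT1 at 2.39, LHT1 at 1.21 and AAP6 at -1.13. In all, 8438 of 17285 tested genes were called, 4311 higher and 4127 lower, with 1180 and 382 of them changed at least 2-fold.

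**Figure D3:**
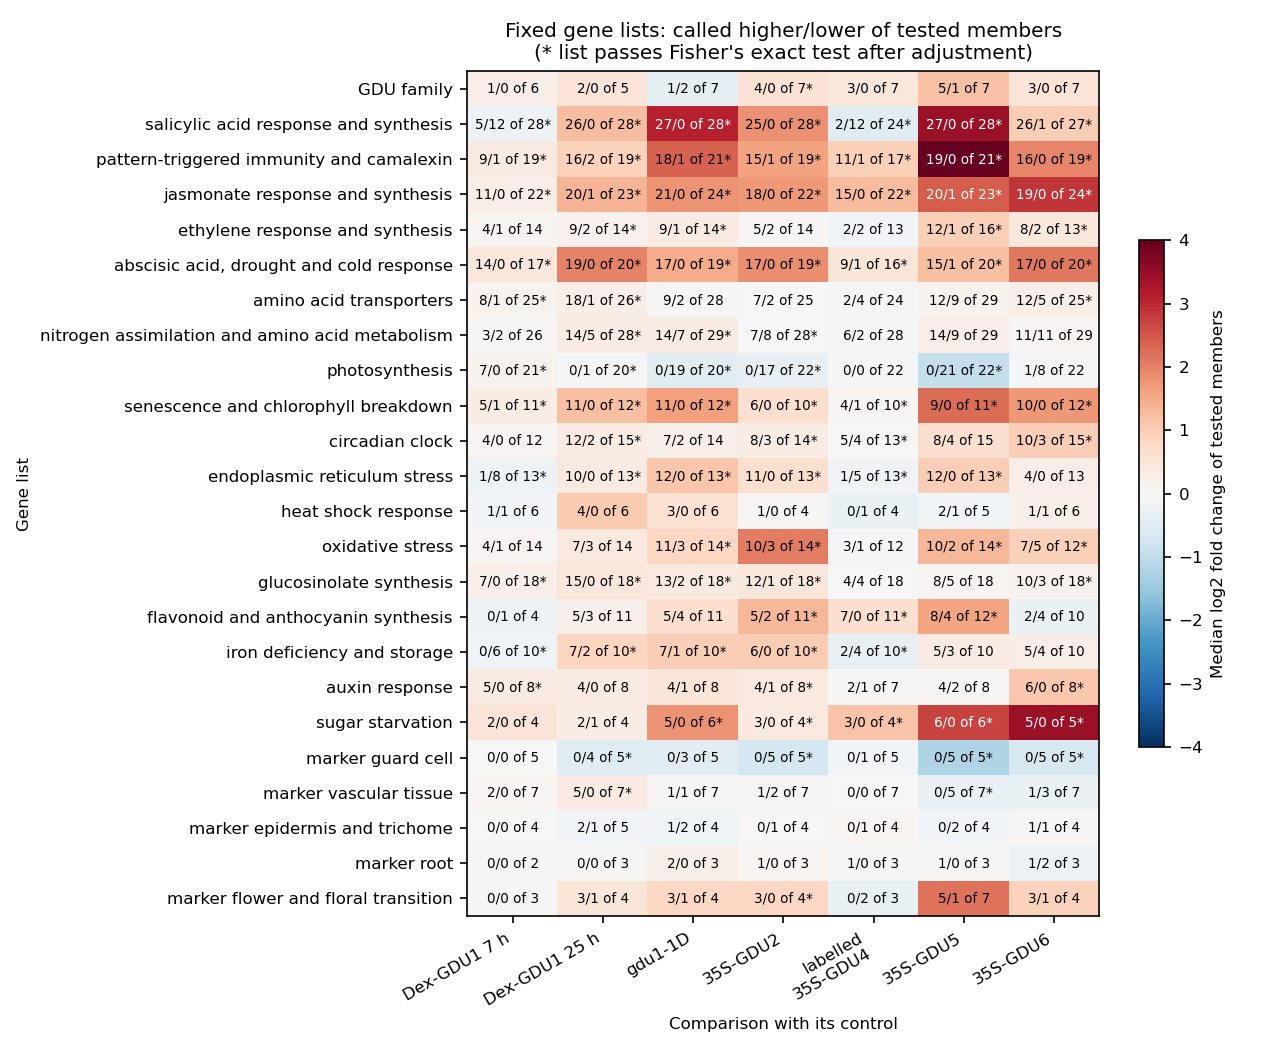
Median log2 fold change (colour, scale ending at -4 and 4) and called members (higher/lower of tested) of each of the 24 fixed gene lists in the 7 comparisons; a star marks an adjusted p below 0.05 by Fisher's exact test in either direction, including fewer calls than among other genes. Salicylic acid genes have 12 lower members in Dex-GDU1 at 7 h and in the libraries labelled 35S-GDU4, and from 25 to 27 higher members in the other 5 comparisons.

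Called genes were compared between lines, in 21 pairs of comparisons. Genes raised in all 7 comparisons numbered 418, and 16 genes were lower in all 7. No expected count was computed for these, and the constitutive comparisons share the Col wild type libraries, so they are not 7 separate observations. The libraries labelled 35S-GDU4, where no rise of GDU4 was measured, are among them. Foremost among the raised genes were the defence regulators WRKY53 and WRKY40, CNI1, the ethylene response factor genes ERF6 and ERF-1, the jasmonate synthesis gene AOC3, BT2 and ORA47, with log2 fold changes of WRKY53 from 1.67 in Dex-GDU1 at 7 h to 6.20 in 35S-GDU5. Touch-induced genes, a list added after seeing the data, were called higher in 10 or 11 of 12 cases in each comparison, so handling was not separated from these shared rises. Dex-GDU1 at 25 h and gdu1-1D, which share no library, had 4979 genes called in the same direction against 1797 expected by n1 × n2 / N, or 93.2% of the genes called in both. Their log2 fold changes had a Pearson r of 0.69 across genes, which are not independent replicates. Dex-GDU1 at 7 h and 25 h had 1926 genes in the same direction against 636 expected, and Dex-GDU1 at 7 h and gdu1-1D 1635 against 611. Dex-GDU1 at 7 h and the libraries labelled 35S-GDU4 shared 782 against 212. Pearson r across genes was 0.42 for this pair and from 0.22 (gdu1-1D) to 0.41 (35S-GDU6) for the other pairs with Dex-GDU1 at 7 h. Dex-GDU1 at 25 h and the libraries labelled 35S-GDU4 shared 1014 against 601, with 796 genes in opposite directions, and in the lower direction 199 against 216 (Fisher's exact adjusted p 0.189).

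The 10 pairs of constitutive lines share the Col wild type libraries, so part of their overlap can come from those libraries, which could not be split. For gdu1-1D, 3680 genes were called in the same direction in 35S-GDU2 against 954 expected, 5974 in 35S-GDU5 against 2153 and 5285 in 35S-GDU6 against 1875. The covariance of log2 fold changes across genes was 0.406 for gdu1-1D and 35S-GDU2 against 0.104 simulated from shared controls alone, 0.768 against 0.145 with 35S-GDU5, and 0.412 against 0.0985 with 35S-GDU6. For gdu1-1D and the libraries labelled 35S-GDU4 the covariance was 0.0712 against 0.0785 simulated, with 1167 genes in the same direction against 572 expected and 626 in opposite directions. For those libraries it was above the simulated value with 35S-GDU2 (0.101 against 0.0701), 35S-GDU5 (0.227 against 0.0843) and 35S-GDU6 (0.197 against 0.0771). The simulated values rest on standard errors that are upper bounds at the smallest p-value, so they may be too high. That p-value was reached by 4243 genes in gdu1-1D and 1344 in the libraries labelled 35S-GDU4. For this pair, a covariance near the simulated value therefore cannot show that the lines share nothing beyond the controls.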

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

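The tests on low counts, on the control line for the endoplasmic reticulum stress and iron genes, on both explanations for GDU4 and on both explanations for the genes raised in the libraries labelled 35S-GDU4 were chosen after the results were seen. The test on the control line for the salicylic acid genes was set down before its result was seen.

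A difference between the times stood out in Dex-GDU1, where the effect of 2951 genes differed between 25 h and 7 h. Among them were 23 of 28 salicylic acid genes and 11 of 13 endoplasmic reticulum stress genes, all more positive at 25 h. With the standard error from the deposited test statistic, 398 genes differed, among them 17 salicylic acid and 2 endoplasmic reticulum stress genes. A fall of the control line between the times is argued against as the whole cause for the salicylic acid genes, since 89.3% of them were higher at 25 h than at 7 h in Dex-GDU1 itself (median log2 change 0.56 relative to all genes), although the control changed by -0.45, and low counts are argued against too, as the 23 genes with FPKM of at least 5 kept a median difference of 1.18 (95% bootstrap interval 0.90 to 1.73). That interval resampled genes, which can move together, and holds no spread between libraries. For the endoplasmic reticulum stress genes the turn went with a fall of the control line. In Dex-GDU1 itself 38.5% of them (5 of 13) were higher at 25 h, and 11 were lower in the control. The same held for the iron genes, at 10% (1 of 10) and 8 lower in the control. The clock time of sampling differs with the hours since the spray, as may the time since the humidity dome, and both stay open. A late rise of the salicylic acid genes may be a hypothesis for a longer time course.

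GDU4 was not raised in the libraries labelled 35S-GDU4. A swap with another over-expressor of the series is argued against, since the highest other GDU gene stood at 12.9 FPKM there, against 294 FPKM for the least abundant over-expressed GDU gene in its own line. GDU4 reads given to a neighbouring gene are argued against as well, since the largest rise among the 47 genes of the same stretch was 20.4 FPKM. Silencing of the transgene, a transgene sequence that the annotation of GDU4 does not cover, and a wrong label from outside the series were not tested and stay open, and no biological explanation was tested.

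Jasmonate, immunity and abscisic acid genes were nonetheless called higher more often than other genes in the libraries labelled 35S-GDU4, with WRKY40, PHI-1 and BT2 leading among well expressed genes. Of the 388 genes at least 2-fold higher there, 368 could be set against Dex-GDU1 at 7 h, which shares no library. Of these, 279 (75.8%) were also called higher in Dex-GDU1 at 7 h, against 7.32% of other genes. This argues against values that vary gene by gene. Early stress genes can move together, so a low state of these genes in the 2 Col wild type libraries could give the same overlap. That explanation stays open. Touch or handling at harvest may have contributed, as 83.3% of touch-induced genes were called higher, but 5 of those 12 genes also stand in other lists. In each of the 7 comparisons 10 or 11 of the 12 were called higher, also in the 2 of Dex-GDU1, which hold no Col wild type library, so a harvest difference of Col wild type does not account for all of these rises. For the libraries labelled 35S-GDU4 it stays open.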

How the results depend on the processing

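The alternative that leaves out entries joining several genes was chosen after seeing the data, and the others were planned. No paired analysis was possible because the tables give 1 value per group, and for the same reason no replicate block, no leave-one-out value and no count of other splits of the samples was computed. Depth per library is unknown, so its effect on these results was not assessed.

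A minimum absolute log2 fold change of 1 lowered the counts of called genes, by its construction, to 180 and 957 for Dex-GDU1 at 7 h and 25 h, 1401 for gdu1-1D, 938 for 35S-GDU2, 495 for the libraries labelled 35S-GDU4, 2902 for 35S-GDU5 and 1562 for 35S-GDU6. With a pseudocount of 1 the same minimum gave, in this order, 111, 516, 959, 613, 343, 2198 and 1053, and with centred values 181, 957, 1402, 933, 499, 2911 and 1564. At q below 0.01, Dex-GDU1 at 7 h kept a count of 1851. Overlaps in the same direction with the minimum were 88 for both times of Dex-GDU1, 75 for Dex-GDU1 at 7 h and gdu1-1D, and 516 for Dex-GDU1 at 25 h and gdu1-1D, and q below 0.01 gave 1086 for the second pair. With the standard error from the test statistic, 398 genes differed between the times, and the cause was not tested. The other 27 counts of called genes, 5 overlaps and 1 count of differing genes stayed within 1.5 times the main value. Of the 140 list results, q below 0.01 brought 7 past the threshold and ended 8 calls. These were amino acid transporters in Dex-GDU1 at 7 h and in 35S-GDU6, photosynthesis in Dex-GDU1 at 25 h, vascular markers there and in 35S-GDU5, flavonoid synthesis in 35S-GDU5, glucosinolate synthesis in 35S-GDU6 and auxin response in 35S-GDU2. The background of genes with FPKM of at least 1 brought 2 and ended 2 (transporters in 35S-GDU6, auxin response in 35S-GDU2), and leaving out joined entries ended the last of these. The pseudocount and centring enter no list call, so they test nothing there.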

Other observations

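The list of cytokinin-induced genes was drawn up after 2 of this family, ARR6 and ARR15, and the synthesis gene IPT3 had been seen among the largest falls, and its members exclude those genes. Its test was set down before the members were seen, but the bootstrap interval was added as a criterion after the result for Dex-GDU1 at 7 h was known, and the test on the control line was chosen after the results were seen.

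Cytokinin-induced genes, mainly type-A response regulators, were called lower more often than other genes in 6 of the 7 comparisons. In 4 of them the 95% bootstrap interval of the median lay below 0. The bootstrap resampled the genes of the list, which can move together, so the interval holds no spread between libraries. The median log2 fold change was -0.74 in Dex-GDU1 at 25 h (8 of 9 lower, Fisher's exact adjusted p 6.87e-05), -0.55 in gdu1-1D (8 of 10 lower, 0.000257), -0.51 in 35S-GDU2 (8 of 9 lower, 1.85e-07) and -0.47 in the libraries labelled 35S-GDU4, where GDU4 was not raised (6 of 9 lower and 1 higher, 4.95e-06). It was -0.92 in 35S-GDU5 (7 of 9 lower and 1 higher, 0.0039, interval -1.11 to 0.10) and -0.50 in 35S-GDU6 (6 of 10 lower and 1 higher, 0.0313, interval -0.95 to 0.17), where the intervals include 0. In Dex-GDU1 at 7 h the median was 0.0227, with 1 lower and 2 higher of 9. By the bound set down first, a median above 0, this value counts against a lower response at 7 h. Its interval, -0.16 to 0.37, includes 0, and by the interval added later the question stays open for that time. ARR7 stood at 23.3 and 36.4 FPKM in 4c-S7 at 7 h and 25 h and at 23.7 and 20.6 FPKM in Dex-GDU1 in the authors' deposited tables. Relative to all genes, the median member changed between the times by 0.55 in 4c-S7 and by -0.07 in Dex-GDU1, where 55.6% of the members (5 of 9) were lower at 25 h, so a rise in the control line alone is not excluded as the source of the difference between the times. A cytokinin response below that of time-matched controls is a hypothesis that these values may support, but the constitutive comparisons share their Col wild type libraries and cannot count as separate evidence. Cytokinin levels or a reporter of cytokinin response, measured at both times, would decide it.

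Levels of QQS and GDU6 differed between the sprayed and the unsprayed sets, which differ in line and spray and were normalised separately. QQS was also called within the comparisons of gdu1-1D (2.37-fold), 35S-GDU2 (1.39-fold), 35S-GDU5 (1.19-fold) and Dex-GDU1 at 7 h (0.74-fold). It was called in 35S-GDU6 (0.34-fold) and the libraries labelled 35S-GDU4 (0.23-fold) as well. QQS stood at 9.04 and 9.46 FPKM in 4c-S7 at 7 h and 25 h and between 45.8 and 50.7 FPKM in Col wild type, and at 116 FPKM in gdu1-1D, 15.4 FPKM in 35S-GDU6 and 10.5 FPKM in the libraries labelled 35S-GDU4, in the authors' deposited tables. GDU6 was listed at 0 in both groups at 7 h and at 0.0750 and 0.334 FPKM in 4c-S7 and Dex-GDU1 at 25 h, without a test, against 9.14 to 10.1 FPKM in Col wild type, in the authors' deposited tables. These genes were chosen after their values were seen.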
